A study of Homo sapiens with 21 samples.

How the data were processed

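Total RNA from Hs746T cells, a human gastric carcinoma line, was measured on 21 Affymetrix expression arrays. The labels put the arrays in 7 groups of 3, described as biological replicates. A control line, passaged in DMSO, was treated for 72 h with 0.1% DMSO, 1 µM cabozantinib or 1 µM crizotinib. 4 resistant lines, 2 for each drug, had been selected by rising doses up to 1 µM and were treated for 72 h with 1 µM of their own drug. Cabozantinib and crizotinib are small molecules that inhibit the MET receptor tyrosine kinase, among other kinases. Groups and replicate numbers were taken from the sample titles. For the crizotinib-resistant samples the source name field reads as cabozantinib-resistant, while the title, the resistance status and the treatment name crizotinib, and the title was followed.

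The values are log2 RMA summaries per probe set, made by the authors, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarizes the probes of each set on the log2 scale. Its version and the probe set definition are not given in the sources used here. The deposited log2 table used here has 34236 rows, 1 of which lacks a value and was left out, so 34235 probe sets were tested. 286 rows repeat the values of another row, so counts of probe sets are not counts of genes. Array medians lay between 2.84 and 2.91. The table carries no detection calls, so no probe set could be called above or below background, and control probe sets were not set apart. The number of arrays per group limits the precision.

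Probe sets are given by identifier. The files used here do not pair these identifiers with gene names. A second deposited table lists gene symbols without probe set identifiers, and its 21 columns of values carry names that match no sample label. Those 21 columns were given to no sample and enter no value reported here. In an earlier exploratory step, symbols had been joined to probe sets by matching the values of rows in both tables. Gene-level results from that join were seen before the probe set analyses were run and before the patterns weighed in the closing section were chosen. The join was then dropped, and no symbol or result from it is used here. The gene list tests that had been planned, and the level of MET, were therefore not analysed here.

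All 21 arrays entered 1 linear model of 7 group means, fitted with limma 3.58.1 (lmFit and eBayes, without trend or robust prior) in R 4.3.3. The fit had 14 residual degrees of freedom and a prior of 2.87. 14 comparisons were drawn from it. P-values were adjusted by Benjamini-Hochberg within each comparison, and a probe set was called at an adjusted p under 0.05 with no minimum fold. The model, the comparisons and most alternative settings were fixed before the data were examined. The tested set departs from that plan. It was to be 1 row per gene symbol, the one with the highest mean, without control probe sets and unnamed rows. Without symbols, all 34235 probe sets were tested, so the adjustment and the counts are not those planned. The planned rule for named genes needed symbols. In its place, by a rule set after the data had been seen, 2 probe sets that rose and 2 that fell are named, those with the largest smaller change over both drugs among sets called with both and with no overlap between the arrays of the groups. With 3 arrays against 3, chance alone leaves 10% of probe sets without overlap in 1 comparison. The rule needed this against DMSO for both drugs, so its chance share is lower and was not computed.

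Acute changes of at least 2-fold were followed into each resistant line. A probe set was counted as moved back when the line differed from the control line on the same drug in the opposite direction, and as still off DMSO when the line differed from the control line on DMSO in the acute direction, each at an adjusted p under 0.05. The share of the acute change that remained is the difference of the line from DMSO divided by that of the drug-treated control line, given as a median over probe sets. Comparisons that share control arrays were set beside 20 simulated data sets with the fitted spread and no effect. To follow the acute changes, 20 more were simulated for each of 2 cases, with the acute effects kept and each resistant line set equal to the control line on its drug or on DMSO. Calls in simulated data were made at the unadjusted p cutoff that the real calls of the same comparison had reached, since an adjustment over data without effects would call almost nothing. This rule was chosen after seeing the data. No resistant line without drug was analysed here, so a difference between a resistant line on drug and the control line on DMSO holds both the line and the drug.

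The fit was tested on simulated data for the acute cabozantinib comparison, with 200 of 34235 probe sets changed. It recovered 37.3% of the changes of 1.5-fold, 70.1% of those of 2-fold and 90.9% of those of 4-fold, with 4 unchanged probe sets called. The real comparison called 17.3% of probe sets, so its adjusted cutoff lies at a larger unadjusted p. These rates therefore hold for sparse changes and do not describe the real calls. Alternatives were a replicate block, a filter on dim probe sets at the 40th percentile of mean signal, quantile normalization again, a shift of each array to the same median, a trended and robust prior, array quality weights, a fit of the compared groups alone, a 2-fold minimum and the omission of each array. Averaging rows by symbol and the second table could not be used for the reason above.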

Results

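Expression was measured in 21 arrays of Hs746T cells, 3 for each of 7 combinations of line and treatment, to describe the response to MET inhibition and the state of lines that grow in the inhibitors. Values are log2 RMA levels of 34235 probe sets, and a difference of 1 is 2-fold. No pair of arrays held identical values. Correlations between arrays of a group ran from 0.9767 to 0.9869, and those between groups from 0.9577 to 0.9796. Each array's mean correlation with its own group was 0.9768 to 0.9796 in the drug-treated control groups and 0.9815 to 0.9866 in the others. The fit takes 1 spread per probe set for all groups. It can therefore understate the spread in comparisons with the drug-treated control groups. The first principal component, with 24.0% of the variance, set the drug-treated control line (scores from -57.8 to -44.2) apart from the DMSO control and all resistant lines (8.6 to 31.5). On the second component, with 13.1%, the DMSO control lay between -57.5 and -50.7, and crizotinib-resistant line 2 between 28.7 and 36.6.

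**Figure D1:**
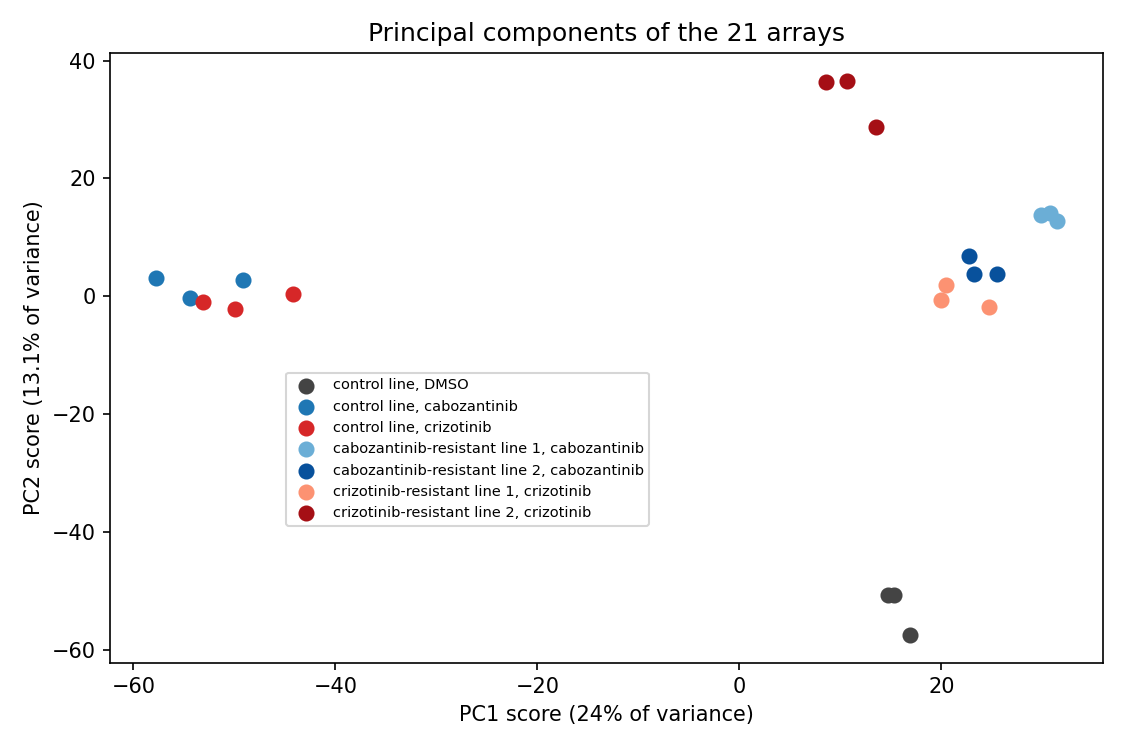
Scores of the 21 arrays on the first principal component (24.0% of variance, horizontal) and the second (13.1%, vertical), each point 1 array and each colour 1 group. The drug-treated control arrays lie at -57.8 to -44.2 on the first component, while all resistant lines on drug lie at 8.6 to 31.5, near the DMSO control on that component and away from it on the second.

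Exposure of the control line to cabozantinib for 72 h raised 2486 probe sets and lowered 3442, which is 17.3% of those tested. Of these, 494 rose and 1034 fell at least 2-fold. Crizotinib raised 2469 and lowered 3132, with 450 rises and 903 falls of at least 2-fold. Probe set 16872926 rose from 4.76 ± 0.30 (SD, n = 3) on DMSO to 9.20 ± 0.10 on cabozantinib and 9.31 ± 0.17 on crizotinib, log2 changes of 4.44 (SE 0.19) and 4.55 (SE 0.19). Probe set 16677556 rose from 4.46 ± 0.33 to 8.47 ± 0.18 and 7.89 ± 0.19. Probe set 16743721 fell from 8.17 ± 0.07 to 3.01 ± 0.46 and 3.19 ± 0.12. Probe set 16753630 fell from 8.01 ± 0.03 to 3.06 ± 0.80 and 3.30 ± 0.74. These drug-treated levels lie near the array medians (2.84 to 2.91) and were not shown to be above background, so both falls can be larger than measured. The adjusted p from limma for these 8 changes lay between 2e-11 and 7.5e-09. Calls were densest among bright probe sets: cabozantinib changed 46.9% of the brightest 25% by mean signal and 2.08% of the dimmest 25%. With the arrays quantile-normalized again, 52.2% of the cabozantinib calls were rises, against 41.9% as deposited. For crizotinib it was 53.9% against 44.1%, so the excess of falls among all calls depends on the scaling. With arrays shifted to the same median, 39.8% and 45.4% were rises. Changes of at least 2-fold with both drugs kept more falls under quantile normalization again, 646 against 443 rises. As deposited these were 750 and 352. A fit of the cabozantinib and DMSO arrays alone called 4133 probe sets, against 5928 in the fit of all groups. For crizotinib it was 3709, against 5601.

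The same probe sets responded to both drugs far more often than in independent lists with every probe set equally likely to be called. That expectation can be too low, since bright probe sets were called more often with either drug. 1764 were higher with both (179 for independent lists) and 2674 lower with both (315), and none went opposite ways. With the arrays quantile-normalized again the counts were 2307 higher and 2098 lower, so which direction is the larger depends on the scaling. Across probe sets, which are not independent replicates, the log2 changes correlated at r = 0.86 with a covariance of 0.210. Both comparisons use the same DMSO arrays, which alone gave r = 0.50 and a covariance of 0.0240 in simulated unchanged groups, with 20 probe sets called higher with both and 19.6 lower on average. Part of the excess in calls may come from those shared arrays, since 3 controls are too few to split.

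Compared directly in the control line, cabozantinib and crizotinib differed at 7 of 34235 probe sets, 1 higher and 6 lower with cabozantinib. An unadjusted p under 0.05 in limma was found for 3215. With no difference anywhere, a share of about 0.05 of the probe sets would pass that cutoff, which is fewer. Among the 1779 probe sets changed at least 2-fold by either drug, the median absolute difference between the drugs was 0.21, and the 95% interval of the difference lay within 2-fold for 1414 (79.5%). The change was larger with cabozantinib for 1153 of the 1779 (64.8%). For the remaining probe sets a difference of 2-fold was not excluded, so a similar action there was not shown. The 7 calls were unstable: leaving out replicates 1, 2 and 3 of the cabozantinib arrays gave 3, 18 and 0, and of the crizotinib arrays 1, 3 and 11. As deposited, 14.3% of the 7 calls were rises, against 25% with quantile normalization again and 0 with arrays shifted to the same median.

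Resistant lines held in drug were set against the control line on the same drug, which asks what distinguishes cells that grow in the inhibitor from cells newly exposed to it. Cabozantinib-resistant line 1 had 3891 probe sets higher and 2787 lower, with 1222 and 518 at least 2-fold. Line 2 had 3292 higher and 2502 lower. Crizotinib-resistant line 1 had 3262 higher and 2628 lower, and line 2 had 2708 and 2262. Independent lists, with every probe set equally likely to be called, would share 2.82 higher and 1.03 lower over all 4 lines. Measured in all 4 lines, 1249 probe sets were higher and 764 lower. With the arrays quantile-normalized again these were 1064 and 985, and the share of higher calls went from 56.8% to 49.0% in cabozantinib-resistant line 2 and from 55.4% to 48.7% in crizotinib-resistant line 1, so the excess of higher calls in those 2 lines depends on the scaling. In cabozantinib-resistant line 1 and crizotinib-resistant line 2 it narrowed, from 58.3% to 51.1% and from 54.5% to 51.6%. With arrays shifted to the same median, 55.4% to 62.5% of calls were higher in the 4 lines. Cabozantinib-resistant and crizotinib-resistant lines, whose comparisons share no arrays, correlated at r = 0.56 to 0.60 across probe sets. The lines of a drug share the control arrays and correlated at 0.76 for cabozantinib and 0.65 for crizotinib, against 0.50 in simulated unchanged groups. Their covariances were 0.187 and 0.135, against 0.0242 and 0.0243. All these comparisons subtract the control line on a drug, and its acute changes correlated at r = 0.86 between the drugs. Lines that merely lacked the acute change would therefore also correlate and share calls. The simulated groups and the independent lists leave this out. A state common to the resistant lines is not shown by these values. Fits of the compared groups alone called 5104 and 3979 probe sets for cabozantinib-resistant lines 1 and 2, against 6678 and 5794. For crizotinib-resistant lines 1 and 2 they called 3502 and 2634, against 5890 and 4970.

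Most of the large acute changes were reduced in the resistant lines. Of the 1528 probe sets that cabozantinib changed at least 2-fold in the control line, 1013 (66.3%) had moved back in cabozantinib-resistant line 1 and 1042 (68.2%) in line 2. Of the 1353 that crizotinib changed, 883 (65.3%) had moved back in crizotinib-resistant line 1 and 726 (53.7%) in line 2. Simulated lines equal to the drug-treated control line gave 25.8, 24.0, 24.4 and 20.6 on average, of about 1898.6 and 1738.3 selected with cabozantinib and crizotinib. Probe set 16753630, which had fallen with both drugs, was higher in all 4 resistant lines than in the control line on drug, by a measured 2.80, 3.98, 2.46 and 3.67 on the log2 scale (SE 0.32; limma adjusted p from 5.8e-08 to 1.6e-05). As the drug-treated control level was not shown to be above background, these differences can be larger than measured. It stood at 5.87 ± 0.05 (SD, n = 3) and 7.05 ± 0.11 in the cabozantinib lines and at 5.76 ± 0.17 and 6.97 ± 0.02 in the crizotinib lines.

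**Figure D2:**
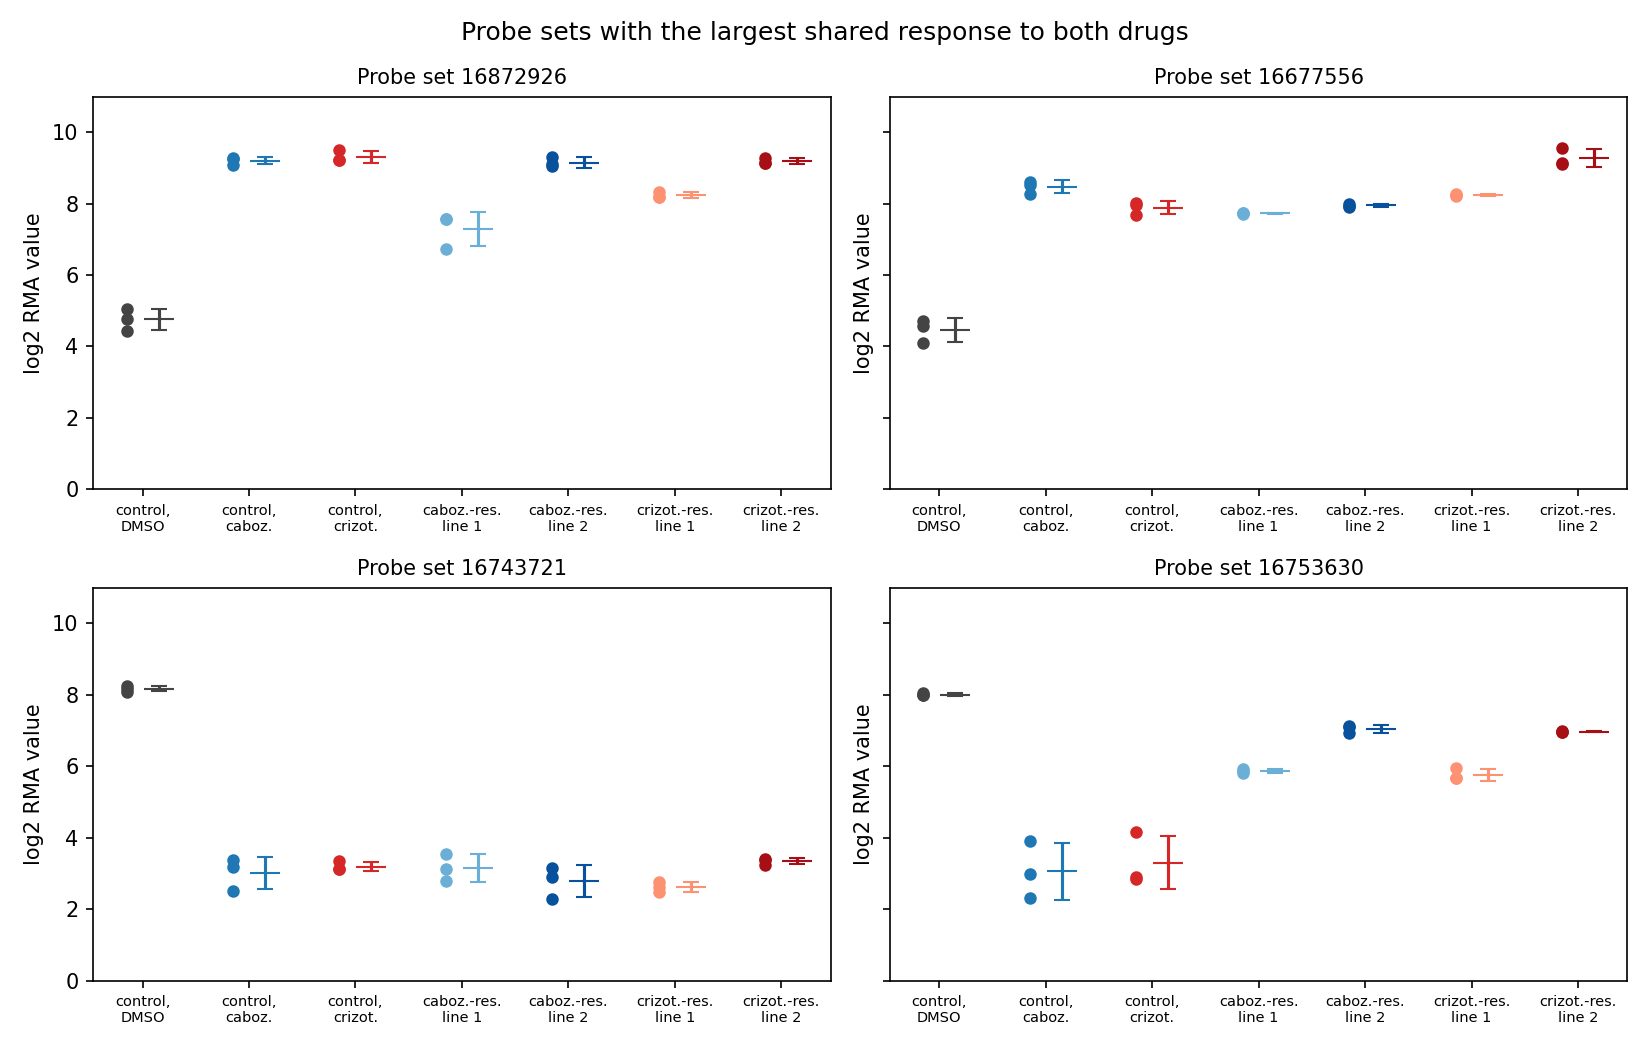
Log2 RMA values (vertical) of the 4 named probe sets in the 7 groups (horizontal); points are single arrays, and the bars beside them are the mean and SD of 3 arrays. Probe set 16743721 stays between 2.63 and 3.34 in group means of every drug-treated group, while 16753630 returns to between 5.76 and 7.05 in the resistant lines.

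Part of the response persisted in every line, and most of it in crizotinib-resistant line 2. Against the control line on DMSO, 735 of the 1528 cabozantinib-changed probe sets (48.1%) were still off in the acute direction in cabozantinib-resistant line 1 and 726 (47.5%) in line 2. For crizotinib it was 686 of 1353 (50.7%) in line 1 and 943 (69.7%) in line 2. The median share of the acute change that remained was 34.6%, 34.7%, 38.9% and 59.0% in that order. Simulated lines equal to the DMSO control gave 23.3, 19.7, 19.2 and 23.8 still off on average. In crizotinib-resistant line 2 the falls were still off in 73.6% of 903 cases and the rises in 61.8% of 450. In the other 3 lines the order was opposite, with 45.9%, 45.8% and 48.9% of the falls and 52.6%, 51.0% and 54.2% of the rises still off, and these differences were not tested. Probe set 16743721 remained lower than on DMSO in all 4 lines (changes of -5.02, -5.38, -5.54 and -4.83). Its level on drug was not shown to be above background in any group, so its differences from the control line on drug (0.14, -0.22, -0.57 and 0.14) do not show whether it changed further. Probe set 16872926 remained 2.53, 4.39, 3.48 and 4.43 above DMSO, and 16677556 remained 3.26, 3.48, 3.78 and 4.80 above it.

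**Figure D3:**
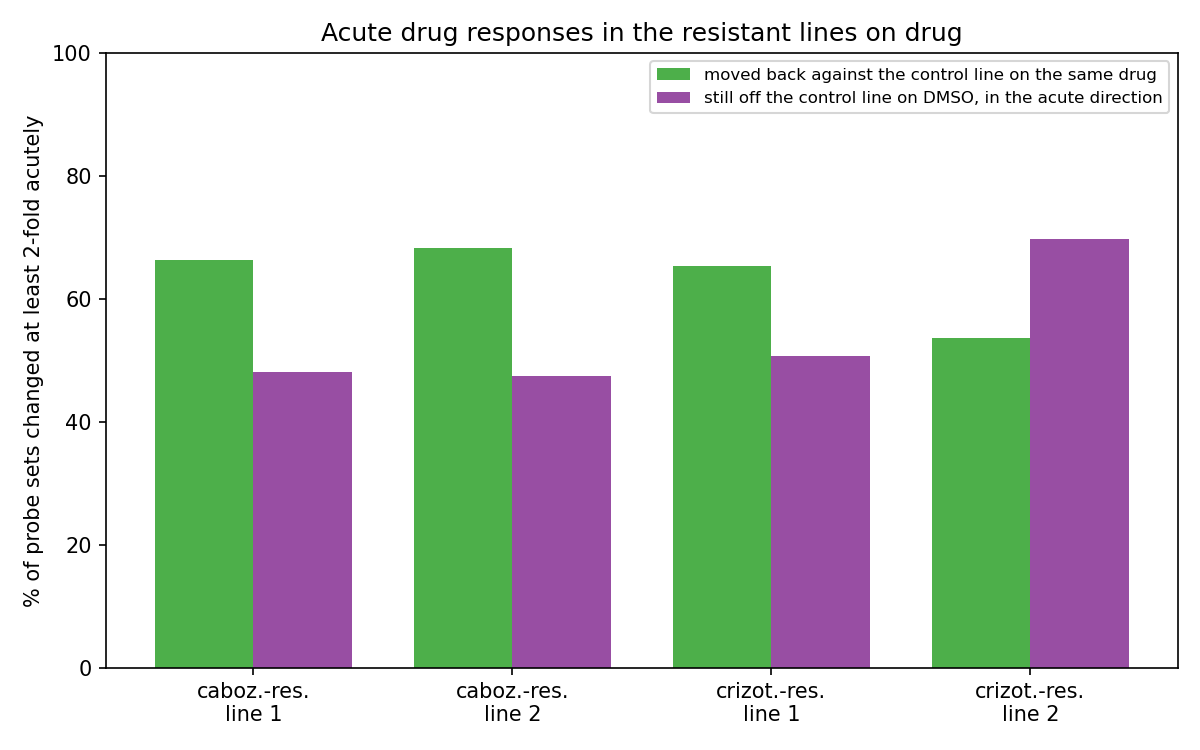
Share (vertical, in %) of the probe sets changed at least 2-fold by the acute drug that moved back or were still off DMSO in each resistant line on drug (horizontal); a probe set can count in both bars. Crizotinib-resistant line 2 had the lowest share moved back, 53.7%, and the highest share still off, 69.7%.

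In total, cabozantinib-resistant line 1 on drug differed from the control line on DMSO at 2801 higher and 2502 lower probe sets, and line 2 at 2077 and 2305. Crizotinib-resistant line 1 had 2313 higher and 2553 lower, and line 2 had 2635 and 3242. With the arrays quantile-normalized again, higher calls went from 47.4% to 50.9% in cabozantinib-resistant line 2, from 47.5% to 51.3% in crizotinib-resistant line 1 and from 44.8% to 52.5% in line 2, so the excess of lower calls there turns with the scaling. 797 were higher and 850 lower in all 4 lines, and 851 and 758 with quantile normalization again, so the larger direction turned here too. Independent lists, with every probe set equally likely to be called, would share 0.884 and 1.19, but all 4 comparisons use the same DMSO arrays. Taken in pairs, they shared 1141 to 1527 higher and 1331 to 1637 lower calls, against 14.5 to 19.9 per direction in simulated unchanged groups, and covariances of 0.105 to 0.144 against 0.0240 to 0.0241. Part of this excess may come from the shared arrays. Of these, 267 higher and 184 lower had been called with neither drug in the control line, 24 and 15 of them at least 2-fold in every line. A probe set not called acutely is not shown to lack an acute change.

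Lines selected in the same drug differed from each other. Cabozantinib-resistant line 2 had 1364 probe sets higher and 1927 lower than line 1, with 154 and 330 at least 2-fold. Crizotinib-resistant line 2 had 1920 higher and 2099 lower than line 1, with 322 and 324 at least 2-fold; 47.8% of its calls were higher as deposited and 53.1% with quantile normalization again. Probe set 16872926 was higher in line 2 of both drugs, by 1.87 (SE 0.19, limma adjusted p = 3.1e-06) for cabozantinib and 0.95 (SE 0.19, adjusted p = 0.002) for crizotinib. Probe set 16753630 was higher in line 2 of both as well, by 1.18 (SE 0.32, limma adjusted p = 0.023) and 1.21 (SE 0.32, adjusted p = 0.017). The cabozantinib call was lost, at 1.15 to 1.20, without any replicate of line 1 or without replicate 1 or 2 of line 2, and the crizotinib call, at 1.16 to 1.20, without replicate 1 or 3 of line 1 or replicate 2 of line 2. A fit of the cabozantinib-resistant lines alone called 2312 probe sets, against 3291, and one of the crizotinib-resistant lines alone 1977, against 4019. Each line was derived a single time, so replicate arrays measure the spread within a line and not between derivations.

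The change on resistance, as the mean of both lines of a drug minus the control line on that drug, was compared between the drugs. It was larger or less negative for cabozantinib at 721 probe sets and the reverse at 416, with 139 and 77 at least 2-fold. With the arrays quantile-normalized again, 626 and 517 were called. The p-values rest on the spread of arrays within 2 fixed lines per drug and not on the spread between lines. They do not show that a difference is owed to the drug. Probe set 16677556 was among the 416, at -1.50 (SE 0.18, limma adjusted p = 2e-04). It was lower than in the drug-treated control in both cabozantinib lines (-0.74 and -0.52) and higher in crizotinib-resistant line 2 (1.38). Crizotinib-resistant line 1 did not pass (0.36, limma adjusted p = 0.13). The call in cabozantinib-resistant line 2 was lost without its replicate 1 (-0.52) or 2 (-0.50), or without replicate 2 (-0.45) or 3 (-0.49) of the control line on cabozantinib. Probe set 16872926 did not pass, with a difference of -0.38. For 16743721 and 16753630 the levels on drug in the control line were not shown to be above background, so no difference is given.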

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

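All tests of explanations and splits in this part were written down after the results they bear on had been seen. 4 differences between groups stood out. Cabozantinib and crizotinib differed at 7 probe sets in the control line, the lines of cabozantinib at 3291, the lines of crizotinib at 4019, and the changes on resistance to the drugs at 1137. For the 7, 2 of the 10 splits of the 6 arrays gave as many calls, the highest other split giving 8. For the lines of cabozantinib and of crizotinib, the highest other splits gave 0 and 1. 10 splits are too few for a share under 0.05. For the 1137, 1 of 100 drawn splits, the real one, gave as many, and the highest other gave 15. These splits mixed arrays of lines that differ, which widens the spread within the mixed groups and leaves few calls. They therefore cannot separate a difference between the drugs from chance differences between whole lines.

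The first pattern is that the 4 resistant lines did not group by drug. The cabozantinib lines against the crizotinib lines gave 3587 calls. Pairing line 1 of each drug against line 2 of each gave 3668, and the third pairing gave 3573, so differences among lines of any origin are a candidate explanation for all of the difference by drug. Quantile normalization again gave 3500 calls. Under this step acute cabozantinib went from 5928 to 5840 calls, while its share of rises went from 41.9% to 52.2%. A stable count can thus hide array-wide differences left by the normalization, and these stay open. With 3 pairings, a drug-specific part stays open and was not tested further.

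The second pattern is that part of the acute change remained in the lines. For falls that ended in bright levels, a floor of the signal is argued against, because the median share remaining among falls that ended in the brightest 25% of levels (over 4.66) was at least 29.0% in every line. For dimmer falls it stays open. Noise in the shared DMSO arrays that is independent between probe sets is argued against as well. Simulated lines equal to DMSO left at most 23.8 probe sets off on average, against at least 686 in the real lines. Both were called at the same unadjusted cutoff. The simulated noise was drawn separately for each probe set and array. A shift common to many probe sets in the DMSO arrays could therefore not appear, and stays open. Whether the remainder reflects drug still acting on its target or a fixed trait of the lines cannot be separated without lines off drug, and may be either.

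The third pattern is the larger remainder in crizotinib-resistant line 2 than in line 1, a difference of 20.1 percentage points in the median share. Leaving out any 1 array kept it at 17.3 or more, which argues against 1 array. Quantile normalization again gave 19.0, which argues against array-wide differences that this step removes. Those it leaves were not tested. A trait of that line is consistent with these values as a hypothesis. The line and any day or batch on which it was grown and processed share the same 3 arrays and were not tested apart.

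Against other splits of their 6 arrays, the remaining comparisons gave the following, each with 1 split of 10 reaching the real count, and 10 too few for a share under 0.05. Acute cabozantinib gave 5928 calls and at most 2 in another split, and acute crizotinib 5601 and 1. The resistant lines against the control line on drug gave 6678 and 0, 5794 and 0, 5890 and 2, and 4970 and 4. Against DMSO they gave 5303 and 0, 4382 and 0, 4866 and 1, and 5877 and 1. Every other split mixed arrays of both groups compared, which widens the spread and leaves few calls wherever the groups differ. The low counts are therefore no further evidence for the real ones.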

How the results depend on the processing

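The alternatives for the 14 comparisons were fixed before the data were examined; those for moved-back, remaining and shared probe sets, for pairings of lines and for the brightest 50% were chosen after seeing the data. No called change of a named probe set turned its direction. The larger direction among calls turned under quantile normalization again in 8 of the 14 comparisons and among probe sets called with both drugs or off DMSO in all 4 lines (851 higher, 758 lower); the cause was not tested. Shifting arrays to the same median turned it in 1 of 14, and left 1732 higher and 2633 lower with both drugs. Of 286 counts and shares recomputed under settings other than leaving out an array, 263 stayed within 1.5 times, and of 504 with 1 array left out, 498 did. Overshoot and single-line counts, and the smaller subsets of sets shared by all lines, were not recomputed. For the named probe sets, 366 of 384 calls with an array left out and 382 of 392 under other settings kept their side of the threshold. Not run for lack of symbols were the average of rows per symbol, the second table and all gene list tests. Without detection calls, signal over background was not assessed.

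Requiring at least a 2-fold change, which removes smaller ones by construction, left 1528 and 1353 calls for acute cabozantinib and crizotinib, 3 for their difference, 1740, 1347, 1312 and 1124 for the 4 resistant lines against the control line on drug, 1175, 902, 973 and 1497 against DMSO, 484 and 646 between lines of a drug, and 216 for the drugs' difference on resistance. Fits of the compared groups alone have fewer arrays behind the spread and take it only from those groups. They called 4133 and 3709 for acute cabozantinib and crizotinib, and 0 for their difference (7 in the fit of all groups). For the resistant lines against the control line on drug they called 5104, 3979, 3502 and 2634, and against DMSO 4801, 3517, 3674 and 4824. Between lines of a drug they called 2312 and 1977, and for the drugs' difference on resistance 927. Fewer arrays and unequal spreads of the groups were not tested apart as causes of the lower counts. The 7 calls between the drugs also became 21 among bright probe sets, 28 with a trended and robust prior and 0 with array weights; the cause was not tested.

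Same-numbered arrays deviated together little, with correlations between -0.054 and 0.049 over all probe sets. A weak shared deviation in some pairs of groups is not excluded. Over the 21 pairs of groups, the highest value of the lowest same-number correlation was 0.032, and 0.052 among the brightest 50%, and 9 of 21 arrays correlated best with their own number, so the numbers were not read as pairing. With the replicate block the 7 calls became 1, and the other counts recomputed with it stayed within 1.5 times.

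With each array left out in turn, calls ran over 4882 to 5437 and 4600 to 5068 for acute cabozantinib and crizotinib and 0 to 18 for their difference. For the 4 lines on drug they ran over 5728 to 6216, 4835 to 5226, 5047 to 5388 and 4185 to 4644, against DMSO 4358 to 4561, 3602 to 3669, 4039 to 4265 and 4839 to 5346, between lines 2561 to 2648 and 3159 to 3480, and for the difference on resistance 845 to 1057. The recomputed counts of moved-back, remaining and shared probe sets stayed within 1.5 times.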

Other observations

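Of the probe sets changed at least 2-fold in the same direction by both drugs, 352 rose and 750 fell. In all 4 resistant lines, 148 of the rises and 391 of the falls had moved back, and 131 of the rises and 235 of the falls were still off DMSO. 30 rises and 46 falls had moved back in all 4 and differed from DMSO in none at an adjusted p under 0.05. At the other end, 15 rises and 47 falls stayed off DMSO in all 4 lines and differed from the drug-treated control line in none, where falls that ended near background could not show a further change.

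Some probe sets differed from DMSO against the direction of their acute change. Of the 1528 changed by cabozantinib, 76 in line 1 and 57 in line 2 did, and of the 1353 changed by crizotinib, 52 and 36. Over all probe sets and both directions, 15.5%, 12.8%, 14.2% and 17.2% differed from DMSO in the same order of lines. The counts are in a single direction and these shares in both. The acute changes were also selected against the same DMSO arrays, whose noise works against overshoot. The comparison therefore cannot decide whether overshoot is a trait of the acute changes. Of all probe sets, 573 were called higher in at least 1 resistant line and lower in another against the control line on drug, and 4293 were called in a single line.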
